A study of Mus musculus with 7 samples.

How the data were processed

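Gene expression was measured on 7 Affymetrix Mouse Gene 1.0 ST arrays, per the labels. Each array held RNA from 1 pool of lung CD11b+ conventional dendritic cells (cDC2s), sorted as CD11c+ MHC-II+ CD11b+ Ly6C- CD64- cells from 10 female mice. House dust mite extract, at 100 µg, or saline (PBS) had been given to the mice 12 hours earlier. The labels put 2 arrays in the group of PBS-treated wild type mice, 2 in house dust mite-treated wild type and 3 in house dust mite-treated Irf3-deficient mice. No PBS-treated Irf3-deficient group was analysed here.

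The deposited values are log2 expression values for 35556 probesets, and their range and medians fitted that unit. R 3.2.1, the oligo package and RMA are named per the submitters' processing notes, which give no roles or order. RMA is the usual method of background correction, quantile normalisation between arrays and summary of probes into probesets. Such a normalisation gives all arrays nearly the same distribution, so a change shared by most transcripts could not be seen in these values. The array medians lay between 7.60 and 7.69. No detection call accompanied the values, and no scan date or other batch was given in the sources used here.

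Probesets were named through the platform annotation, in which 21789 probesets carried 1 gene symbol, 1621 carried several and 12146 were not listed. Only probesets with 1 symbol were used. Symbols were updated through Entrez identifiers in a table of RefSeq genes of the GRCm38.p6 assembly, which matched 19856 of the 19939 genes. Of the 998 genes with several probesets, the probeset with the highest mean over the 7 arrays was kept, and no filter on brightness was applied. The labels and the values name no genome build, so no coordinates are given, and the RefSeq table served only for names, for genomic spans and for which genes lie near each other. Genes of near-identical families (Ifit, Ifi200, Slfn, Oas, Gbp and Phf11 genes) may share probes, and their values are uncertain as to the family member.

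All 7 arrays were fitted with 1 mean per group in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend), which left 4 residual degrees of freedom and added 8.34 prior degrees. The contrasts were treated against untreated wild type, treated Irf3-deficient against treated wild type, and treated Irf3-deficient against untreated wild type. Tests were two-sided, adjusted by the Benjamini-Hochberg method over 19939 genes, with a threshold of 0.05, and every adjusted p-value of a gene below comes from this limma fit. A gene "rose" or "fell" only where it passed that threshold. Log2 fold changes are given with the standard error of the moderated fit, fold changes with a 95% confidence interval, and group means with their SD.

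The design, the tests, the alternatives, 25 gene lists and the rule for named genes were fixed before the data were examined. Of 580 listed genes, 525 were measured by a probeset of their own. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists of a comparison. Repeats with an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction without setting them against other genes, were the alternatives. Members that passed were counted with p-values adjusted over all genes and adjusted over the list alone. The named genes are Irf3, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap (leaving out predicted genes without a known product), from each list up to 2 members per direction with the smallest p, and a panel of 20 genes. Isg15, a member of that panel, had no probeset of its own. Other genes are named where stated, after their values were seen.

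The comparison of treated against untreated wild type and that of Irf3-deficient against wild type share the treated wild type arrays with opposite signs. Correlations, covariances and overlaps between them were therefore set beside values simulated for unchanged groups sharing those arrays. Positional enrichment around Irf3 was tested with a one-sided Fisher's exact test.

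The fit was tested on simulated data with 200 changed genes among 19939, drawn 10 times per comparison. At a true change of 1.5-fold it recovered 81.2% of the changed genes for the wild type response, 89.7% for Irf3-deficient against wild type, and 90.1% for Irf3-deficient treated against untreated wild type. At 2-fold it recovered 99.7%, 100% and 100%. False genes made up 7.07%, 7.18% and 7.15% of the calls, above the nominal 5%. With all members of the cholesterol list changed by 1.5-fold, camera called that list in 10 of 10 runs. It called an unchanged list 4 times over the 24 other lists of each run. The simulated genes were drawn independently, so these runs do not test camera on lists whose genes are correlated. In the real data the estimated correlation reached 0.627, for interferon-stimulated genes.

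Alternatives covered brightness filters, the mean of a gene's probesets, 3 further normalisations, 2 variance models, fits on the arrays of the compared groups alone, array weights, the replicate number as a block, a test against a change of 1.2-fold and leaving out each array in turn. Probesets with several symbols or none in the annotation were left out of all comparisons and are summarised only in the closing section.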

Results

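Conventional dendritic cells carry inhaled antigen from the lung to the lymph node and prime T cells, and the CD11b+ subset (cDC2) is the one sorted here. House dust mite extract, a common allergen that also contains microbial products, was given to wild type mice and to mice lacking Irf3, a transcription factor that switches on type I interferon genes downstream of several innate sensors. Expression was compared 12 hours after 100 µg of extract or PBS in 7 pools of cDC2s, each from 10 mice: 2 from PBS-treated wild type, 2 from treated wild type and 3 from treated Irf3-deficient mice. The design addresses how lung cDC2s respond to the allergen and how that response differs without Irf3. Arrays of 1 group correlated at 0.995 to 0.997 over all genes, and arrays of different groups at 0.973 to 0.990. On the first principal component, with 54.0% of the variance, the treated wild type arrays lay at 34.6 and 40.9 and the other 5 arrays between -19.0 and -12.1. The second component, with 26.2%, placed the untreated wild type arrays at 28.0 and 18.5 and the Irf3-deficient arrays between -17.8 and -14.6. In an F test over the 3 groups, 5090 of 19939 genes (25.5%) passed.

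Irf3 itself followed the labels in every array. Its log2 level was 9.48 and 9.56 in untreated wild type, 9.59 and 9.57 in treated wild type, and 8.26, 8.13 and 8.30 in the Irf3-deficient arrays. The Irf3-deficient mean of 8.23 ± 0.09 (SD, n = 3) lay 2.56-fold below the treated wild type mean (95% CI 2.18 to 2.99, adjusted p = 2.11e-06). Which exons the probes cover was not given in the sources used here, so the remaining signal cannot be assigned to background or to a shortened transcript. Treatment left Irf3 at a difference of 0.06 in wild type (adjusted p = 0.801). Bcl2l12, which neighbours Irf3, differed by -0.19 between the treated genotypes (adjusted p = 0.32).

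In wild type cDC2s, house dust mite raised interferon-stimulated genes more than any other fixed list. It raised genes of dendritic cell maturation and of MHC class I presentation, and lowered macrophage-type and cell cycle genes. None of these lists passed with an estimated correlation between genes. The schlafen gene Slfn1 rose 28.8-fold (95% CI 19.2 to 43.2), the antiviral enzyme Rsad2 rose 24.7-fold (18.6 to 32.9), and Irf7, a transcription factor that amplifies interferon production, rose 16.5-fold (13.2 to 20.6). All 39 measured interferon-stimulated genes rose, also adjusted over the list alone, with a median log2 change of 2.72. Oasl1 rose by 4.15 ± 0.13 (SE, adjusted p = 2.97e-09) and the antiviral GTPase gene Mx2 by 3.66 ± 0.13 (adjusted p = 4.4e-09). Slfn4, Ifit1, Ifit2, Ifit3, Ifit3b and Ifi213 completed the 10 largest rises, at log2 changes between 4.13 and 4.70, although members of these families may share probes. The list passed at adjusted p = 3.52e-62 in camera, with adjusted p = 0.102 with an estimated correlation. Ifnb1, the gene of interferon beta, rose from 6.53 ± 0.26 to 7.82 ± 0.19 (SD, n = 2 each), a log2 change of 1.28 (adjusted p = 0.000133) that starts among the dimmest genes.

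Dendritic cell maturation and migration genes rose as a group in the same comparison, with 28 of 35 higher and 0 lower (30 and 0 adjusted over the list alone; median 1.07). The list passed at adjusted p = 3.31e-27, against adjusted p = 0.102 with an estimated correlation. The interleukin 15 receptor chain Il15ra rose by 2.46 (adjusted p = 1.95e-08) and the interleukin 2 receptor chain Il2ra by 2.29 (adjusted p = 8.24e-09). The costimulatory genes Cd40 and Cd86 rose by 1.56 ± 0.13 and 1.07 ± 0.12 (SE), and Ccr7, the receptor that guides dendritic cells to lymph nodes, by 0.57 ± 0.07. In the same arrays 16 of 22 monocyte and macrophage markers fell. Slco5a1 and H2-M2, at -0.19 and -0.13, did not pass. Of 14 MHC class I presentation genes, 10 rose and 0 fell (10 and 1 adjusted over the list alone), among them the class I transactivator Nlrc5 by 1.86 (adjusted p = 3.47e-07) and the immunoproteasome subunit Psmb9 by 1.57 (adjusted p = 4.21e-07). This list passed at adjusted p = 1.08e-10 and stood at adjusted p = 0.0505 with an estimated correlation. MHC class II presentation showed no shift, with 2 of 14 genes higher and 2 lower (the same counts adjusted over the list alone; adjusted p = 0.733).

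Cytokine genes moved in both directions. Of 38 inflammatory cytokines and chemokines, 14 rose and 4 fell (17 and 7 adjusted over the list alone; adjusted p = 0.00494, and adjusted p = 0.699 with an estimated correlation). Il15 rose by 2.30 (adjusted p = 6.61e-07), Il12b by 1.77 (adjusted p = 1.9e-07), Il6 by 1.33 (adjusted p = 0.000908), Cxcl10 by 2.72 (adjusted p = 2.04e-07) and Ccl5 by 1.26 (adjusted p = 1.38e-06), while the chemokine genes Ccl6 and Ccl9 fell by 0.70 and fell by 0.51. Signals linked to T helper 2 priming did not shift as a list, with 8 of 29 higher and 6 lower (12 and 7 adjusted over the list alone; adjusted p = 0.315). Within it Pdcd1lg2 rose by 1.60 and Tnfsf4, the gene of OX40 ligand, by 1.10, while Cd200r1 fell by 0.87 and the lectin gene Mgl2 fell by 0.56. Ccl22 rose by 0.48 (adjusted p = 0.000578). Ccl17 stood at 0.18 (adjusted p = 0.0872), Il33 at 0.35 (adjusted p = 0.123) and Il10 at -0.28 (adjusted p = 0.517). NF-kB target and feedback genes rose in 8 of 21 cases and fell in 2 (8 and 4 adjusted over the list alone; adjusted p = 0.00471, and adjusted p = 0.519 with an estimated correlation), led by the apoptosis inhibitors Birc2 at 1.38 and Cflar at 1.12. In the IRF3 pathway list, 6 of 19 rose and 3 fell (10 and 4 adjusted over the list alone; adjusted p = 0.039, and adjusted p = 0.241 with an estimated correlation). Irf9 rose by 1.12, whereas the sensor component Cd14 fell by 1.38 and the adaptor gene Ticam2 fell by 0.71.

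Markers of monocytes and interstitial macrophages, cells that the CD64- Ly6C- gate should leave out, were mostly lower after treatment. In that list 16 of 22 fell and 4 rose (17 and 4 adjusted over the list alone; median -1.25; adjusted p = 2.05e-08, and adjusted p = 0.138 with an estimated correlation). Adgre1, a surface receptor gene of macrophages, fell by 2.05 ± 0.13 (SE, adjusted p = 3.47e-07), the scavenger receptor gene Cd163 fell by 1.88 and the lipid carrier Apoe fell by 2.03. The largest falls of all also held Col14a1, Abca9, Fcrls, Il1rl2, F13a1, Itgb5 and Ms4a7, at log2 changes between -2.26 and -1.89. The 4 risers included Plac8 at 2.82 and Ms4a4c at 1.36. Genes of cDC2 identity fell in 11 of 23 cases and rose in 4 (14 and 4 adjusted over the list alone; adjusted p = 0.000566, and adjusted p = 0.102 with an estimated correlation). The fractalkine receptor gene Cx3cr1 fell by 1.46 and Itgam, which encodes CD11b, fell by 1.06, while Cd7 rose by 1.45 and Relb by 1.08. Irf4 and Flt3, at -0.08 and -0.19, did not pass.

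Cell cycle genes fell in 20 of 35 cases and rose in 0 (27 and 0 adjusted over the list alone; median -0.57; adjusted p = 1.08e-10, and adjusted p = 0.46 with an estimated correlation), among them Stmn1 by a log2 change of -0.83 and Rrm1 by -0.75. Cholesterol biosynthesis genes rose in 11 of 19 cases and fell in 0 (13 and 2 adjusted over the list alone; adjusted p = 6.7e-06, and adjusted p = 0.115 with an estimated correlation), with Hmgcs1 at 1.18 (adjusted p = 1.73e-05). Immediate early genes fell in 10 of 25 cases and rose in 5 (12 and 5 adjusted over the list alone; adjusted p = 0.0194, and adjusted p = 0.519 with an estimated correlation), with Myc at -0.80 and Nr4a3 at 0.81. Lung epithelial, endothelial and stromal markers fell in 9 of 23 cases and rose in 1 (the same counts adjusted over the list alone; adjusted p = 0.00109, and adjusted p = 0.241 with an estimated correlation). Epcam fell by 0.94 and the surfactant gene Sftpb fell by 0.70, and the riser was Kdr, a receptor for vascular endothelial growth factor, at 2.63.

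The other 11 lists did not pass in this comparison. Rises and falls numbered 3 and 7 of 17 for cDC1 markers, led by Itgb8 at 1.97 and Cadm1 at -0.88, and 6 and 2 of 22 for T and NK cell markers, with Cd8a at 1.41 and Cd2 at -1.12. They numbered 4 and 5 of 16 for alveolar macrophage markers, 3 and 2 of 19 for neutrophil markers, 5 and 1 of 17 for B cell and plasmacytoid dendritic cell markers, and 0 and 2 of 15 for eosinophil, mast cell and basophil markers. For erythrocyte and platelet markers they were 0 and 1 of 6, for glycolysis and hypoxia 2 and 3 of 21, for antioxidant and NRF2 targets 4 and 2 of 18, for the unfolded protein response 3 and 4 of 20, and for neighbours of Irf3 1 and 2 of 19. Adjusted over the list alone, the counts differed for T and NK cell markers (9 and 2), neutrophil markers (4 and 2), B cell and plasmacytoid dendritic cell markers (5 and 2), glycolysis (3 and 4), NRF2 targets (5 and 2) and the unfolded protein response (4 and 4). Their adjusted p-values in camera lay between 0.16 and 0.956. Median and mean differed in sign for glycolysis and hypoxia (-0.16 and 0.05) and for neutrophil markers (-0.02 and 0.01), and the test leaned down for eosinophil, mast cell and basophil markers against a median of 0.06.

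In all, 3505 of 19939 genes passed in wild type, 1664 higher and 1841 lower, and 669 of them differed at least 2-fold (468 higher, 201 lower). At an unadjusted p under 0.05, 5586 genes passed. Groups did not overlap for 52.6% of genes, against 33.3% by chance. Without replicate 2 of treated wild type, 2333 genes passed, 1247 higher and 1086 lower, and without replicate 1 of untreated wild type 1178 were lower. Which direction held more genes depended on the scaling, with 1734 higher and 1653 lower after median centring.

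**Figure D1:**
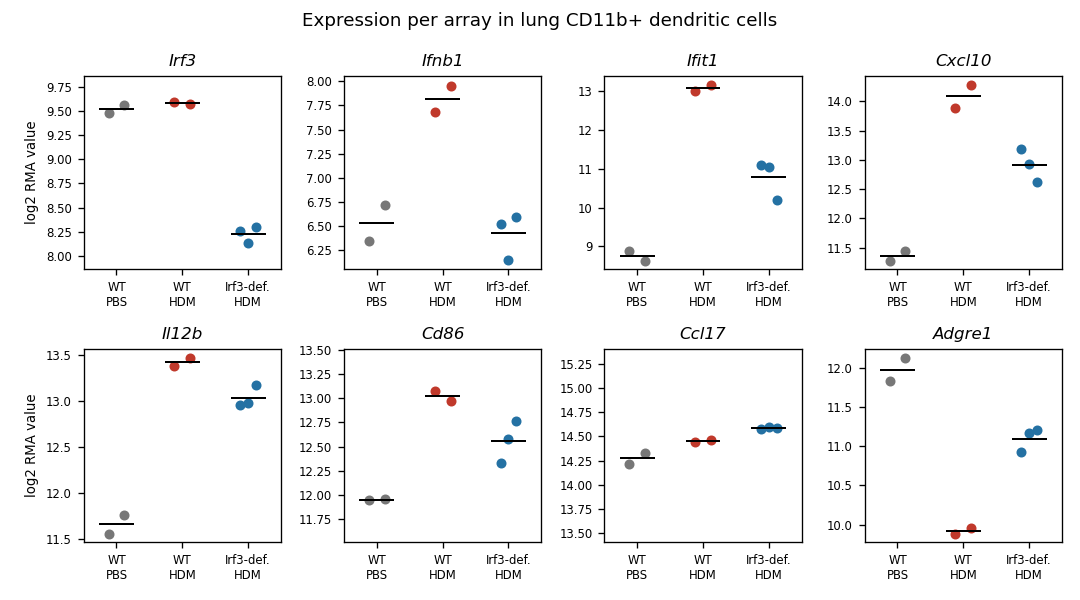
Log2 RMA values of 8 genes on each array (points) with the group mean (bar) in PBS-treated wild type, treated wild type and treated Irf3-deficient cDC2s; the y axes differ between genes. Irf3 was lower in the 3 Irf3-deficient arrays than in the 4 wild type arrays, and Ifnb1 in these 3 lay with untreated wild type.

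Between the treated genotypes, Irf3-deficient cDC2s had lower levels of every measured gene of the interferon-stimulated list. They also had lower MHC class I presentation and maturation genes, and higher levels of many macrophage-type and cDC2 genes. Of these lists, only MHC class I presentation also passed with an estimated correlation. All 39 interferon-stimulated genes were lower, also adjusted over the list alone, with a median log2 difference of -2.08. The list passed at adjusted p = 6.12e-55, against adjusted p = 0.167 with an estimated correlation. Slfn4 was 18.4-fold lower (95% CI 15.2 to 22.2) and Iigp1, an interferon-induced GTPase, 9.37-fold lower (7.32 to 12.0). Mx2 fell by 2.74 ± 0.11 (SE, adjusted p = 2.44e-08), Dhx58 by a difference of -2.18 and Cxcl10 by -1.17. The lowest differences also held Slfn1, Ifi206, Ifi208, Ifi213, Ifi214, Ifit2, Ifit3b and the lipocalin gene Apod, between -3.80 and -3.11. Ifnb1 was 2.63-fold lower (95% CI 2.10 to 3.29, adjusted p = 3.62e-05), at 6.43 ± 0.24 (SD, n = 3). That level lay below 7.11, among the dimmest genes on the arrays, so the fold may be understated.

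Of the 14 MHC class I presentation genes, 11 were lower and 1 higher in Irf3-deficient cells (11 and 2 adjusted over the list alone; adjusted p = 5.9e-11). This was the only list of the comparison that also passed with an estimated correlation, at adjusted p = 0.0455. The immunoproteasome subunits Psmb10 and Psmb9 differed by -1.68 and -1.64, and the chaperone gene Calr was the member that was higher, by 0.40. Dendritic cell maturation and migration genes were lower in 21 of 35 cases and higher in 2 (22 and 2 adjusted over the list alone; median -0.46; adjusted p = 5.73e-10, and adjusted p = 0.286 with an estimated correlation). Il15ra differed by -1.70, Tnfrsf4 by -1.47, Cd40 by -0.56 (adjusted p = 0.00373) and Cd86 by -0.46 (adjusted p = 0.00993), while H2-M2 was higher by 1.09 and Tnfrsf9 by 0.56. Ccr7 differed by -0.10 (adjusted p = 0.336). In the IRF3 pathway list 9 of 19 were lower and 3 higher (9 and 5 adjusted over the list alone; adjusted p = 0.0418, and adjusted p = 0.286 with an estimated correlation), with Ccl5 at -1.55 and Ifna4 at -0.91 against Cd14 at 1.26 and Ticam2 at 1.05.

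Markers of monocytes and interstitial macrophages were higher in Irf3-deficient cells in 14 of 22 cases and lower in 5 (15 and 5 adjusted over the list alone; adjusted p = 0.000595, and adjusted p = 0.351 with an estimated correlation). Fn1, the fibronectin gene, was higher by 1.52 and Adgre1 by 1.17, while Plac8 was lower at -2.69 and Ms4a4c at -1.76. Genes of cDC2 identity were higher in 11 of 23 cases and lower in 3 (14 and 4 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.167 with an estimated correlation), with Clec4a2 at 1.17 and Cx3cr1 at 1.08 against Relb at -0.97 and Cd7 at -0.85. Alveolar macrophage markers were higher in 4 of 16 cases and lower in 1 (5 and 2 adjusted over the list alone; adjusted p = 0.0418, and adjusted p = 0.286 with an estimated correlation), led by the mannose receptor gene Mrc1 at 1.26. Antioxidant and NRF2 targets were higher in 7 of 18 cases and lower in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.00909, and adjusted p = 0.374 with an estimated correlation). Gclm, a subunit of the enzyme that limits glutathione synthesis, was higher by 1.23 and the pentose phosphate enzyme Taldo1 lower, at -0.96. T and NK cell markers were lower in 7 of 22 cases and higher in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.0344, and adjusted p = 0.351 with an estimated correlation), with Gzmb at -1.13 and Cd8a at -1.02.

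Single genes were also much higher in Irf3-deficient cells. St6galnac2, a sialyltransferase gene, was 12.9-fold higher (95% CI 10.5 to 15.8) and the globin gene Cygb 4.28-fold higher (3.52 to 5.21); they neighbour each other on chromosome 11 in the GRCm38.p6 assembly, and between the wild type groups they differed by -0.18 and 0.16 without passing. The chemokine receptor gene Ccr9, a member of the list of B cell and plasmacytoid DC markers, was 6.08-fold higher (5.03 to 7.35) and the mitochondrial arginase gene Arg2 3.99-fold higher (3.35 to 4.76). Rnase2a, Cd209d, Mtmr9, Tcim and Plxdc2 were higher by 1.92 to 2.47. Sympk counts among the 10 largest rises by the rule at 2.22, but another of its 3 probesets gave -0.21, so that value is doubtful. In the cytokine list 12 of 38 genes were higher and 9 lower (14 and 10 adjusted over the list alone; adjusted p = 0.693). Il15 differed by -2.71 (adjusted p = 1.12e-07), Ccl4 by -1.52 and Il6 by -0.68, and Ccl7 was higher by 1.42 and Ccl9 by 0.69. Il12b differed by -0.39 (adjusted p = 0.0117) and Il10 by 0.84 (adjusted p = 0.016). The treated wild type arrays disagreed on Il10, whose wild type response was -0.759 without replicate 2 of that group and 0.198 without replicate 1. The size of its difference between the genotypes therefore depends on these arrays.

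T helper 2 priming signals did not shift as a list between the treated genotypes, with 10 of 29 higher and 7 lower (13 and 8 adjusted over the list alone; adjusted p = 0.284). The C-type lectin genes Clec4e, which encodes Mincle, and Clec4n, which encodes Dectin-2, were higher by 1.70 and 1.01. Tnfsf4 differed by -0.93 (adjusted p = 0.00024), Pdcd1lg2 by -0.62 (adjusted p = 0.0174), Icosl by -0.55 and Il33 by -0.53 (adjusted p = 0.012). Ccl17 and Ccl22 stood at 0.13 (adjusted p = 0.181) and 0.03 (adjusted p = 0.857), Irf4 at 0.31 (adjusted p = 0.0609) and Flt3 at -0.15 (adjusted p = 0.579). Among the other lists that did not pass, genes higher and lower numbered 7 and 3 of 20 for the unfolded protein response (adjusted p = 0.0528), 2 and 6 of 19 for cholesterol biosynthesis (adjusted p = 0.104), 5 and 0 of 19 for neutrophil markers, and 2 and 1 of 35 for cell cycle genes. They numbered 2 and 6 of 21 for NF-kB targets, 2 and 4 of 23 for lung epithelial, endothelial and stromal markers, 6 and 4 of 25 for immediate early genes, 1 and 3 of 14 for MHC class II presentation and 5 and 3 of 17 for cDC1 markers. In the stromal list Kdr was lower, at -2.74, and Epcam higher, at 1.78. For glycolysis and hypoxia the numbers were 4 and 3 of 21, for B cell and plasmacytoid dendritic cell markers 1 and 4 of 17, for eosinophil, mast cell and basophil markers 0 and 0 of 15, and for neighbours of Irf3 1 and 0 of 19. Erythrocyte and platelet markers, with 2 and 0 of 6, had a median of -0.02 and a mean of 0.28, so median and mean differed in sign, as they did for immediate early genes (0.04 and -0.06). For B cell and plasmacytoid dendritic cell markers the test leaned down against a median and a mean of 0.01. Adjusted over the list alone, the counts differed for cholesterol biosynthesis (3 and 7), neutrophil markers (5 and 3), NF-kB targets (3 and 6), stromal markers (3 and 6), MHC class II (2 and 3), cDC1 markers (6 and 5), glycolysis (5 and 4), B cell markers (2 and 4) and erythrocyte and platelet markers (2 and 2).

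Between the treated genotypes 3933 genes passed, 2139 higher and 1794 lower in Irf3-deficient cells, and 569 differed at least 2-fold (188 higher, 381 lower). At an unadjusted p under 0.05, 5769 genes passed, and groups did not overlap for 43.7% of genes against 20% by chance. Without replicate 2 of treated wild type, 2562 genes passed, 1276 higher and 1286 lower. After cyclic loess 1833 were higher and 2052 lower, so the balance of directions depended on the scaling. Genes near Irf3 on chromosome 7 were not called more often than others, with 84 of 465 within 20 Mb (18.1%) against 19.8% elsewhere (one-sided Fisher's exact test, p = 0.84). Without an untreated Irf3-deficient group, a difference between the treated genotypes cannot be assigned to the response rather than to the baseline.

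Treated Irf3-deficient cDC2s still differed from untreated wild type in many of the genes that define the response, in a comparison that changes genotype and treatment together. Interferon-stimulated genes were higher in 31 of 39 cases and lower in 0 (34 and 0 adjusted over the list alone; median 0.76; adjusted p = 2.31e-23, and adjusted p = 0.359 with an estimated correlation). Ifit1 was 4.07-fold higher (95% CI 2.94 to 5.64), Oasl1 was higher by 1.51, Cxcl9 by 1.33 and Cxcl10 by 1.54, whereas Iigp1 and Ifi35 stood at -0.21 and -0.17 without passing. Ifnb1 differed by -0.11 (adjusted p = 0.744) and Ccl5 by -0.28 (adjusted p = 0.0587). Maturation and migration genes were higher in 26 of 35 cases and lower in 0 (28 and 0 adjusted over the list alone; median 0.54; adjusted p = 1.03e-23, and adjusted p = 0.272 with an estimated correlation). Il2ra was higher by 1.65, Cd274 by 1.17, Cd40 by 1.00, Cd86 by 0.61 and Ccr7 by 0.46. MHC class I presentation genes did not differ as a list, with 2 of 14 higher and 0 lower (2 and 1 adjusted over the list alone; adjusted p = 0.681).

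Il12b was higher than in untreated wild type by 1.38 (adjusted p = 4.46e-06) and Cxcl3, a neutrophil attractant, by 1.97 (adjusted p = 1.66e-05), in a cytokine list with 12 of 38 higher and 1 lower (14 and 2 adjusted over the list alone; adjusted p = 1.11e-05, and adjusted p = 0.464 with an estimated correlation). Il6 stood at 0.65 (adjusted p = 0.0556) and Il10 at 0.56 (adjusted p = 0.14). T helper 2 priming signals were higher in 11 of 29 cases and lower in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.00037, and adjusted p = 0.359 with an estimated correlation), with Clec4e at 1.64, Pdcd1lg2 at 0.98, Ccl22 at 0.51 and Ccl17 at 0.31. Tnfsf4, at 0.17, and Il33, at -0.18, did not pass, nor did Irf4 at 0.23 and Flt3 at -0.34. Antioxidant and NRF2 targets were higher in 7 of 18 cases and lower in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.00473, and adjusted p = 0.359 with an estimated correlation), led by the cystine transporter gene Slc7a11 at 1.72. The unfolded protein and integrated stress response had 6 of 20 genes higher and 2 lower (7 and 2 adjusted over the list alone; adjusted p = 0.045, and adjusted p = 0.359 with an estimated correlation), and Asns, the asparagine synthetase gene, was 4.31-fold higher (95% CI 3.48 to 5.34). Cholesterol biosynthesis genes were higher in 8 of 19 cases and lower in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.000138, and adjusted p = 0.304 with an estimated correlation), with Idi1 at 1.45. NF-kB targets were higher in 7 of 21 cases and lower in 1 (12 and 2 adjusted over the list alone; adjusted p = 0.00191, and adjusted p = 0.442 with an estimated correlation). Neutrophil markers were higher in 3 of 19 cases and lower in 0 (4 and 0 adjusted over the list alone; adjusted p = 0.045, and adjusted p = 0.623 with an estimated correlation); they included Lcn2, an iron-binding lipocalin gene, at 2.01 and Clec4d at 1.03.

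Other lists were lower than in untreated wild type. Cell cycle genes were lower in 16 of 35 cases and higher in 0 (22 and 1 adjusted over the list alone; adjusted p = 5.85e-13, and adjusted p = 0.359 with an estimated correlation), with Stmn1 at -0.97 and Birc5 at -0.81. Lung epithelial, endothelial and stromal markers were lower in 9 of 23 cases and higher in 1 (11 and 1 adjusted over the list alone; adjusted p = 3.21e-07, and adjusted p = 0.272 with an estimated correlation), with the surfactant genes Sftpc at -1.12 and Sftpb at -0.99 and, against them, Epcam at 0.84. Monocyte and macrophage markers were lower in 5 of 22 cases and higher in 0 (the same counts adjusted over the list alone; adjusted p = 0.000138, and adjusted p = 0.359 with an estimated correlation), and Apoe was 8.17-fold lower (95% CI 6.23 to 10.7). Immediate early genes were lower in 6 of 25 cases and higher in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.00255, and adjusted p = 0.359 with an estimated correlation). Outside the lists, Arg2 was 11.4-fold higher (9.56 to 13.6) and the oxysterol hydroxylase gene Cyp7b1 4.16-fold higher (3.22 to 5.36), while Qpct, which encodes glutaminyl cyclase, was 6.30-fold lower (5.16 to 7.69), Trim13 4.60-fold lower (3.61 to 5.86) and Cd101 4.03-fold lower (3.02 to 5.37). The lowest 10 also held the histone gene H2ac4 and the small RNA genes Scarna13, Snord73b, Snord104, Snora16a and Snord33, between -2.18 and -1.78. The median level of small RNAs other than microRNAs differed between arrays of 1 wild type group by up to 0.549.

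The other 11 lists did not pass against untreated wild type. Genes higher and lower numbered 3 and 3 of 23 for cDC2 identity, 3 and 3 of 17 for cDC1 markers, 3 and 2 of 16 for alveolar macrophage markers, 3 and 0 of 17 for B cell and plasmacytoid dendritic cell markers, and 2 and 1 of 22 for T and NK cell markers. They numbered 1 and 1 of 14 for MHC class II presentation, 1 and 1 of 19 for the IRF3 pathway, and 2 and 0 of 21 for glycolysis and hypoxia. Of the remaining lists, eosinophil, mast cell and basophil markers had 0 and 0 of 15, erythrocyte and platelet markers 1 and 0 of 6, and neighbours of Irf3 0 and 1 of 19. Adjusted over the list alone, the counts differed for cDC2 identity (4 and 5), alveolar macrophage markers (5 and 3), the IRF3 pathway (4 and 4) and neighbours of Irf3 (0 and 0). Their adjusted p-values lay between 0.123 and 0.974. Median and mean differed in sign for cDC1 markers (0.03 and -0.00246), and the test leaned down for the IRF3 pathway against a median of 0.04.

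In all, 2153 genes passed, 1175 higher and 978 lower, with 200 at least 2-fold different (114 higher, 86 lower), 4573 at an unadjusted p under 0.05, and no overlap of groups for 39.1% of genes against 20% by chance. Without replicate 1 of untreated wild type 749 genes passed, and without replicate 2 of the Irf3-deficient group 1377 did. The balance of directions depended on the scaling here too, with 980 higher and 1035 lower after cyclic loess, and on the arrays, with 722 higher and 782 lower without replicate 2 of untreated wild type and 479 higher and 270 lower without replicate 1.

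**Figure D2:**
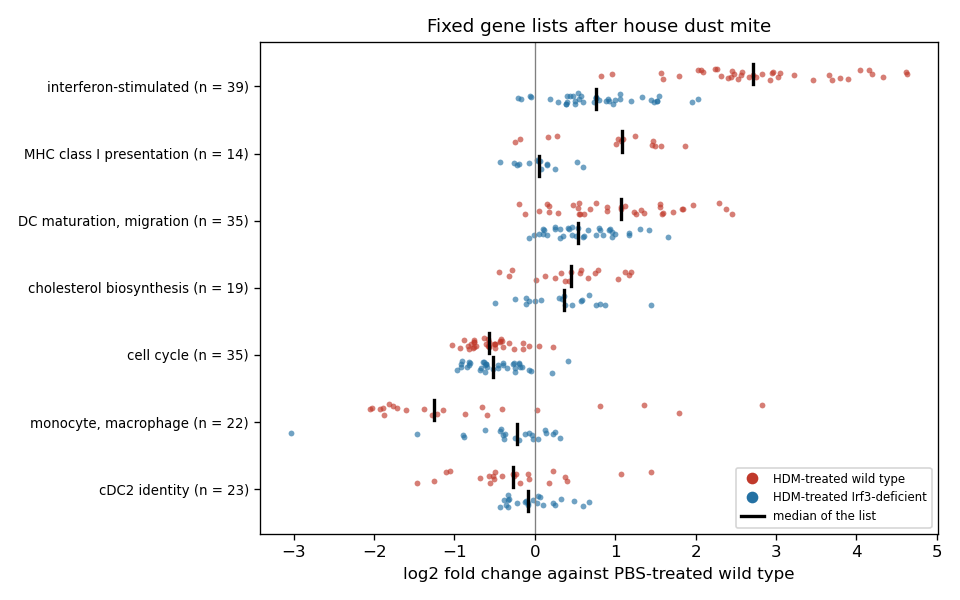
Log2 fold change against untreated wild type of each measured gene (points) of 7 fixed lists in treated wild type and treated Irf3-deficient cDC2s, with the median of each list (bar). Interferon-stimulated genes had a median of 2.72 in wild type and 0.76 in Irf3-deficient cells, and cell cycle genes had medians of -0.57 and -0.53.

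Many genes that house dust mite changed in wild type differed between the treated genotypes in the opposite direction. Of the 1664 genes that rose, 1075 (64.6%) were lower in Irf3-deficient cells, where 149.7 would be shared by independent lists, and of the 1841 that fell, 1051 (57.1%) were higher, where 197.5 would be. With the treated wild type arrays split, 1 in each comparison, a test chosen after the data were seen, 736 of 1247 risers and 632 of 1086 fallers were shared in the opposite direction, where independent lists would share 91.2 and 98.5. With the arrays exchanged, 752 of 1419 and 602 of 1685 were shared, where 91.5 and 107.8 would be. An excess thus remained where no treated wild type array was shared. Genes with the same direction in both comparisons numbered 30 and 10. Across genes, which are not independent replicates, the 2 sets of log2 changes correlated at -0.756, against -0.548 in simulated unchanged groups that share those arrays. The simulated correlation holds only where no gene changes, so covariance is the closer measure of what shared arrays add. The covariance of -0.122 lay 0.114 below the simulated -0.00798. Without replicate 2 of treated wild type, the genes shared in opposite directions numbered 1367 in place of 2126.

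Over the 3505 genes called in wild type, the change in treated Irf3-deficient cells against untreated wild type had a slope of 0.295 on the wild type change. A simulated group without response gave 0.01 through the shared untreated arrays. That simulation did not repeat the selection of called genes, so 0.01 may understate what the shared arrays add. The changes of the 2 treated genotypes against untreated wild type correlated at 0.451 across genes, below the 0.548 of simulated unchanged groups that share the untreated arrays. That simulated correlation, too, holds only where no gene changes. By covariance, the closer measure, the 0.0534 found lay above the simulated 0.00799. Of the 1664 risers, 502 (30.2%) also lay above untreated wild type in Irf3-deficient cells, against 98.1 for independent lists. Among them 229 were at the same time lower than in treated wild type, including Ifit1, Cxcl10, Cd40, Cd86 and Il12b, and 243 had no call between the genotypes, including Ccr7 and Ccl22. Another 846 risers were lower than in treated wild type and not called above untreated wild type, including Ifnb1, Ccl5, Il15 and Tnfsf4. These 846 hold 32 genes that were called below untreated wild type. Of the 1841 genes that fell, 439 (23.9%) also lay below untreated wild type, against 90.3 for independent lists. With the untreated arrays split, again after the data were seen, 239 risers and 119 fallers were shared in the same direction, where independent lists would share 30.4 and 17.8, and with the arrays exchanged 261 and 160, where 45.0 and 46.2 would be. Among all genes that fell, 972 were higher than in treated wild type and not called below untreated wild type, including Fn1, Cd14 and Cx3cr1. These 972 hold 53 genes that were called above untreated wild type.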

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

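The values come from the planned comparisons, and the genes named here were chosen after their values were seen. The first group consists of genes whose change against untreated wild type had opposite directions in the 2 treated genotypes, with both changes and the difference between the genotypes passing in limma. There were 32 genes that rose in treated wild type and lay below untreated wild type in treated Irf3-deficient cells, where independent lists would share 81.6. They included Ifi27l2a, which rose by 1.94 in wild type and stood at -0.91 in Irf3-deficient cells (difference -2.86, adjusted p = 1.52e-07), the chemokine gene Ccl4 at 0.77 and -0.75, Ms4a6b at 1.75 and -0.58, and Pttg1 at 1.08 and -0.92. There were 53 genes with the opposite pattern, where independent lists would share 108.5. They included Cd209d at -1.47 in wild type and 0.65 in Irf3-deficient cells, Trem1 at -0.83 and 0.81, Clec4d at -0.47 and 1.03, Epcam at -0.94 and 0.84, Plxdc2 at -1.41 and 0.51, and Rnase2a at -1.01 and 1.46. No biological explanation was tested for these genes, since the baseline of Irf3-deficient cells was not measured.

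The second group consists of signals in probesets that the comparisons did not use. Among 1621 probesets with several symbols, 76 passed for the wild type response (66 higher, 10 lower) and 175 between the treated genotypes (37 higher, 138 lower). Among 12146 probesets not listed in the annotation, 138 passed for the wild type response (105 higher, 33 lower) and 437 between the treated genotypes (176 higher, 261 lower). These probesets cannot be given a gene here.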

How the results depend on the processing

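All alternatives were planned before the data were examined, except the test with split arrays, which was chosen after seeing the data. With the treated wild type arrays split between the comparisons, 1368 and 1354 genes were shared in opposite directions. Under the filters, normalisations, variance models, array weights and fits on the compared groups alone, the counts of called genes stayed within 1.5 times those given, at 3058 to 3577 for the wild type response, 3778 to 4196 between the treated genotypes and 1930 to 2355 against untreated wild type. A test against a change of 1.2-fold left 1399, 1434 and 475 genes, fewer by its construction. The balance of directions was less stable: cyclic loess gave 1737 higher and 1686 lower genes for the wild type response, and the 1.2-fold test 675 higher and 759 lower between the treated genotypes. Leaving out 1 array at a time gave 2333 to 3725, 2562 to 3906 and 749 to 2359 genes, 4025 to 4821 in the F test and 1367 to 2045 genes shared in opposite directions. The lowest of these values came without replicate 2 of treated wild type, except 749, which came without replicate 1 of untreated wild type; the 1377 genes without replicate 2 of the Irf3-deficient group are a further low count. A lone array left in a group was assumed to vary like the other groups, and the cause was not tested. Windows of 5 Mb and of the whole chromosome around Irf3 gave odds ratios of 0.770 and 0.762 beside 0.892.

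The list calls depended on the correlation between genes. With an estimated correlation 0, 1 and 0 lists passed in place of 12, 9 and 13 for the wild type response, the treated genotypes and the comparison with untreated wild type. The adjusted p of the maturation list became 0.102, 0.286 and 0.272 and that of interferon-stimulated genes 0.102, 0.167 and 0.359. With fry, which does not set a list against other genes, 10, 11 and 8 lists passed in the same order. The adjusted p in fry was 0.000262, 0.00367 and 0.00283 for the maturation list. For interferon-stimulated genes it was 0.000339, 0.00118 and 0.0248. Between the treated genotypes, 5 lists passed without the dimmest genes under both brightness filters, and the cause was not tested. Without 1 array, 10 to 12, 6 to 10 and 11 to 13 lists passed. Both named lists kept their direction and their call when any 1 array was left out, with adjusted p of interferon-stimulated genes up to 1.46e-14 and of the maturation list up to 2.3e-09. Apart from the estimated correlation and fry, 385, 367 and 377 of 397 list values per comparison kept their side of the threshold.

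With the replicate number as a replicate block, 3118, 3249 and 1426 genes passed. The samples share only a number: the deviations of same-numbered arrays correlated between -0.233 and 0.178, so they were not treated as paired, and the cause of the lower count of 1426 was not tested.

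Of the named genes, 86 of 128, 87 of 133 and 71 of 128 kept direction and side of the threshold in every alternative that gave them a value. Fits on the compared groups alone were not made for them, and the brightness filters removed some of them. The genes that changed sign had no call on either side of zero where they did so, but Dcn and Il10 passed for the wild type response without replicate 2 of treated wild type, with adjusted p = 0.0493 and 0.0143. For all of them the cause was not tested. For the wild type response, leaving out 1 array gave Dcn -0.124 to 0.6495, Tpx2 -0.0511 to 0.494, Gp9 -0.0231 to 0.203, Irf4 -0.172 to 0.00652, Flt3 -0.430 to 0.0492, Slco5a1 -0.410 to 0.0271 and Il10 -0.759 to 0.198. Between the treated genotypes Flt3 ranged from -0.387 to 0.0918, and Ccl22 stood at -0.0481 with cyclic loess. Against untreated wild type the ranges were -0.113 to 0.0941 for Eno3, -0.2852 to 0.152 for Slco5a1, -0.295 to 0.0788 for Ifnb1 and -0.358 to 0.00728 for Il33. Eno3 stood at 0.0123 with the replicate block, and Ifi30 at -0.0478 after a second quantile normalisation and -0.0917 with cyclic loess. Without detection calls, signal over background could not be judged gene by gene, which limits dim genes such as Ifnb1.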

Other observations

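The tests of this section were not part of the design fixed before the data were examined. Those of genomic neighbours and of monocyte and macrophage markers were chosen only after the results were seen. For transcript length and small RNAs the bounds were set before the tests were run, but for a pattern already seen in the results. The genes below that fall outside the named genes were picked after their values were seen. Besides the genes that answered house dust mite, 412 genes were higher and 294 lower in Irf3-deficient cells than in both wild type groups without a call between the wild type groups, 23 of them at least 2-fold higher and 39 at least 2-fold lower. Among the higher genes, Olr1, a receptor for oxidised lipoprotein, was higher than in treated wild type by 1.47 (adjusted p = 2.7e-05), Pglyrp1, a peptidoglycan recognition protein, by 1.49, and Tnfrsf10b, a death receptor, by 1.18. The transporter gene Abca5 was higher by 1.51. Among the lower genes were Klrd1, which encodes the lectin receptor CD94, at -1.15, the mucin gene Muc1 at -1.06 and Ero1b, an oxidase of the endoplasmic reticulum, at -1.24.

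In Irf3-deficient arrays 3 neighbouring genes of chromosome 11 in the GRCm38.p6 assembly stood far above both wild type groups: BC018473, St6galnac2 and Cygb. BC018473, a noncoding gene, had log2 levels of 6.41 and 6.45 in untreated wild type, 6.55 and 6.80 in treated wild type, and 13.44, 13.21 and 12.65 in Irf3-deficient arrays, a difference of 6.42 (adjusted p = 1.9e-09) between the treated genotypes. Its wild type levels lay below 7.11, among the dimmest genes on the arrays, so that difference may be understated. Of the 18 genes tested within the same 1 Mb, Mxra7 was also higher by 1.63, Snhg16 by 0.73 and St6galnac1 by 0.82. Mir6516 and Gm8624 were lower, at -0.86 and -0.62, and the others had no call between the treated genotypes. Mir6516 stood at 7.56 and 8.68 in treated wild type and was not called against untreated wild type (-0.51, adjusted p = 0.263). Chance placement is argued against by a permutation of gene positions, which put as many of the 23 genes within 1 Mb in a share of 0.0049 of 10000 permutations. Sequence variants of another strain under the probes weaken hybridisation where wild type carries the probed sequence, as its C57Bl/6 label gives. The Irf3-deficient samples carry the same C57Bl/6 label. As the source of the rises they are argued against, for the genes concerned, by Mxra7 and Snhg16, which were also called higher than both wild type groups. St6galnac1 was called higher too, but at adjusted p = 0.0478 against treated wild type and with levels of 7.95, 9.02 and 7.78 in Irf3-deficient arrays. The bound of at least 3 such genes was set after the values were seen. It was met only with St6galnac1, so for the other rises the test decides nothing. For the lower genes such variants were not tested. A genetic difference of the Irf3-deficient colony near these genes may be the source. Without an untreated Irf3-deficient group it cannot be told apart from an effect of Irf3 loss. That 0 of the 3 genes had a house dust mite call in wild type decides nothing, since genes with such a call were not picked. Mxra7, in the same window, had one, at -0.54 (adjusted p = 0.0313).

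Short transcripts were among the genes lower in Irf3-deficient arrays than in both wild type groups. Of 71 small RNAs tested, 28 were called lower than both and 0 higher, among them Scarna13 at -2.22 and the Y RNA gene Rny3 at -1.33 against treated wild type, and short coding transcripts such as Rps29 at -1.10 and Tomm7 at -1.07 moved likewise. A recovery of small RNAs that differs between RNA preparations may be the source, since their median level also differed by up to 0.549 between arrays of 1 wild type group, with deviations of 0.473 and -0.0478 in untreated wild type and 0.0878 and 0.637 in treated wild type, against -0.473, -0.381 and -0.343 in the Irf3-deficient arrays. A length-dependent difference between arrays was left open. The 15136 protein-coding genes without a house dust mite call were grouped into 10 bins by genomic span, a stand-in for transcript length. The median of the shortest bin minus that of the longest was -0.0629 between the treated genotypes and -0.0498 against untreated wild type. The former lay between the bounds of 0.05 and 0.1 set beforehand for that comparison. Its bootstrap interval of -0.0761 to -0.0528 resampled genes and does not measure the spread between arrays. By array, with each gene set against its mean over all arrays, the difference was 0.0332 and 0.00605 in untreated wild type. It was 0.0528 and 0.0204 in treated wild type, and -0.0417, -0.00343 and -0.0537 in Irf3-deficient arrays. An effect of Irf3 loss on these RNAs stays open as well, untested.

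Monocyte and macrophage markers were lower in treated wild type and higher again in treated Irf3-deficient arrays. The 16 that fell had a median of -1.66 in treated wild type and -0.313 in Irf3-deficient cells, both against untreated wild type, and 14 of them were higher in Irf3-deficient than in treated wild type cells. A share of these cells in the Irf3-deficient sorts back at the untreated level stays open. Of the 16, 4 stayed below untreated wild type: Apoe at -3.03, F13a1 at -1.46, Cd163 at -0.90 and Adgre1 at -0.88. By a bound set after the values were seen, these 4 would count against it. They cannot decide it, since expression within the cDC2s could hold single members low at any cell share. Apoe lay even below its level in treated wild type. A smaller share of monocytes or macrophages in the treated wild type sorts stays open. Its test, in which 0 members rose besides 4 known to be induced by interferon (Plac8, Fcgr1, Ms4a4c and Fcgr4), decides nothing, since it set aside every member that rose. cDC2s express many of these genes themselves and the CD64- Ly6C- gate would remove most such cells. A change of expression within the cDC2s, by treatment and genotype, is the biological alternative and stays open too.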
